A study of Mus musculus with 6 samples.

How the data were processed

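Gene expression was measured on single-channel arrays from 6 RNA samples, 3 labelled control and 3 labelled anti-PD-1. Per the labels' protocols, Lewis lung carcinoma (LLC) cells, a mouse lung tumour line, were mixed with Matrigel and 1000000 of them placed under the skin of the left flank. Mice then received 250 µg of an antibody against PD-1, an inhibitory receptor of T cells, or an IgG2a isotype antibody into the peritoneum at intervals of 3 days. The labels call the material tumour tissue, whereas the design text of the series speaks of LLC cells that survived for 7 days after treatment and of control cells without treatment. Both descriptions were left standing, and groups follow the sample labels. RNA input to the biotin labelling was 250 ng, per the labels. Nothing states that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

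The deposited values were log2 signals made at the gene level with SST-RMA, per the file headers, and Transcriptome Analysis Console was named in the submitters' processing notes; its version is not given in the sources used here. The authors' deposited table also held group averages on the log2 scale, group SDs among its other columns, a signed linear fold change (used here as a score, per the file headers), and a p-value with its false discovery rate. The series value table and the workbook held the same signals, with a largest difference of 0. Of 22206 array identifiers 21448 had values; the remaining 758 formed the unbroken end of the workbook and were not used here. Library medians lay between 7.71 and 7.77, and no scanner-level intensity or background was used, so the number of arrays and the rounding of signals to 2 decimals limit the precision.

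Some properties of the deposited table bear on what a value means. The headers and identifiers name a mouse array and the mm10 build, yet the gene symbols, transcript accessions and chromosomes are those of human genes. The authors' averages carry the letters of the opposite group's signals. In 111 rows the averages or SDs do not follow from the signals, at tolerances of 0.05 for an average and 0.02 for an SD. Rows were therefore tested as deposited, with groups taken from the sample labels and gene names taken only from the symbol column of rows with 1 symbol and a chromosome. The build of the positions in the file is unsettled for the same reason. Of the 21448 rows, 20406 had 1 symbol and 1042 had several.

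Differences are anti-PD-1 minus control by sample label. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, group as the sole term, all 6 libraries), with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. A second count took rows at least 2-fold apart at an unadjusted p under 0.05, a rule that does not control the false discovery rate. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with 18620 genes, each represented by its row of highest mean; an estimated correlation and fry were run beside it. Of 38 lists, 37 had at least 5 measured members. The lists, tests, groups, alternatives and rule for named genes were fixed before the data were examined. The rule named the PD-1 receptor and its ligands, and the 12 largest rises and the 12 largest falls past the adjusted threshold. For each described list it named members with the smallest p and any member past the adjusted threshold. List members named below are a selection of these with some others, and are not a ranking by p. The lists had been written with mouse names; their human counterparts were assigned after the symbols were seen, and uncharacterised, antisense and long non-coding loci were added then to the kinds of gene skipped for naming. Levels of sex-specific genes were left out of the per-gene output.

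Principal components used the 2000 rows of largest variance. The alternatives were quantile normalization, median centring, filters on dim rows, 1 row per gene, a trended robust prior, array weights, a block on the replicate number, removal of each library in turn, other thresholds and other list tests. The workbook's signals, equal to those of the series value table, were also run as an alternative. Omission of the 111 rows and an exchange of the group names were added after the data were seen. The fit was tested on simulated data drawn from the means and SDs of the 21448 rows, with 200 rows changed. It recovered 0 of 50 rows changed 1.25-fold, 3 of 50 changed 1.5-fold, 28 of 50 changed 2-fold and 46 of 50 changed 4-fold, with 3 false calls. The 200 changed rows are far fewer than the 6391 that passed in the data. The adjusted threshold was therefore stricter in the simulation, and these shares do not carry over to the data. In 20 simulations over 18620 genes, a list of 24 members shifted by 0.5 was called each time (20 of 20), with 0 calls among 720 tests of unmoved lists. Simulated rows were drawn independently, so these simulations cannot show how often camera calls unmoved lists whose genes are correlated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.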

Results

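Signals of 21448 array rows were compared between 3 libraries labelled control and 3 labelled anti-PD-1, which the series presents as control LLC material and LLC material tolerant of an antibody against the PD-1 receptor. Pearson correlations over rows, which are not independent replicates, ran from 0.9955 to 0.9963 in the 6 pairs of libraries within groups and from 0.9808 to 0.9823 in the 9 pairs between groups. The first principal component held 93.9% of the variance of the 2000 most variable rows and separated the groups, with control libraries between -37.4 and -37.06 and anti-PD-1 libraries between 35.55 and 38.5. The second component held 1.9%.

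The species of the measured genes is in conflict within the deposited table. A mouse array is named in the headers, but 19850 rows carried human Ensembl transcript accessions and 0 rows carried mouse ones. Of 19265 rows with a RefSeq transcript accession, 0 matched the 120299 transcripts of the mouse gene table (GRCm38.p6), and 1299 rows were placed on chromosomes 20, 21 or 22, which the mouse genome lacks. The signals followed the human symbols. Rows named for cytosolic ribosomal proteins (92 rows) had a median log2 signal of 14.98, against at most 10.62 in 10000 random sets of that size, and rows named for olfactory receptors (391 rows), which most tissues do not express, had a median of 4.22, against at least 6.41 in random sets. Gene names below are those of the file and do not settle the species.

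**Figure D1:**
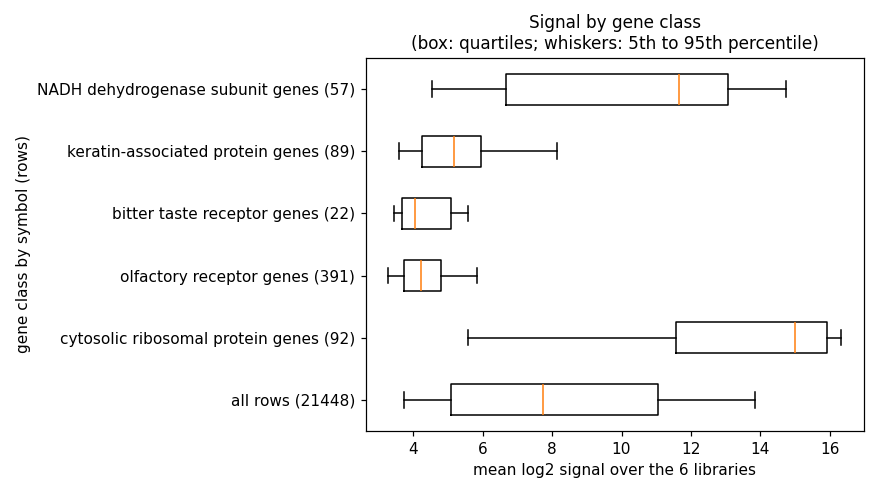
Mean log2 signal over the 6 libraries (x axis) for all rows and for rows grouped by gene symbol (y axis); boxes span the quartiles, the line is the median and whiskers reach the 5th and 95th percentiles. Ribosomal protein rows have a median of 14.98 and olfactory receptor rows one of 4.22, beside 7.743 for all rows.

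The direction of every difference rests on the sample labels and is contradicted by the authors' deposited table. There, averages named C and P matched the signals of the opposite letter in 21363 rows (99.6%) and of their own letter in 2389 rows (11.14%), within 0.05. Among 5099 rows with group averages more than 0.5 apart, 5084 matched with the letters exchanged and 0 as named. If the letters of the averages are right, each rise given here is a fall.

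In 111 rows (0.52%) the averages or SDs in the authors' deposited table did not follow from the signals under either naming. In 47 of them an average lay outside the range of its 3 signals, and in 26 both averages lay outside the range of all 6 signals, with a largest gap of 10.21 on the log2 scale. With the letters exchanged, as in the other rows, signals and averages differed in direction in 31. Genes of mesenchymal transition were frequent among them. VIM, an intermediate filament protein of mesenchymal cells, had mean signals of 18.57 and 19.08 in libraries labelled control and anti-PD-1. Its averages named C and P in the authors' deposited table were 16.01 and 16.06. SNAI1, a repressor of epithelial genes, had mean signals of 6.82 and 7.61 beside averages named C and P of 11.81 and 12.57. For CDH1, the epithelial cadherin, signals of 5.86 and 5.02 stood beside averages named C and P of 12.52 and 12.67. In most other rows the average named C went with the signals of libraries labelled anti-PD-1. No direction is drawn from these rows singly, but the list tests and counts below include them unless said otherwise.

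**Figure D2:**
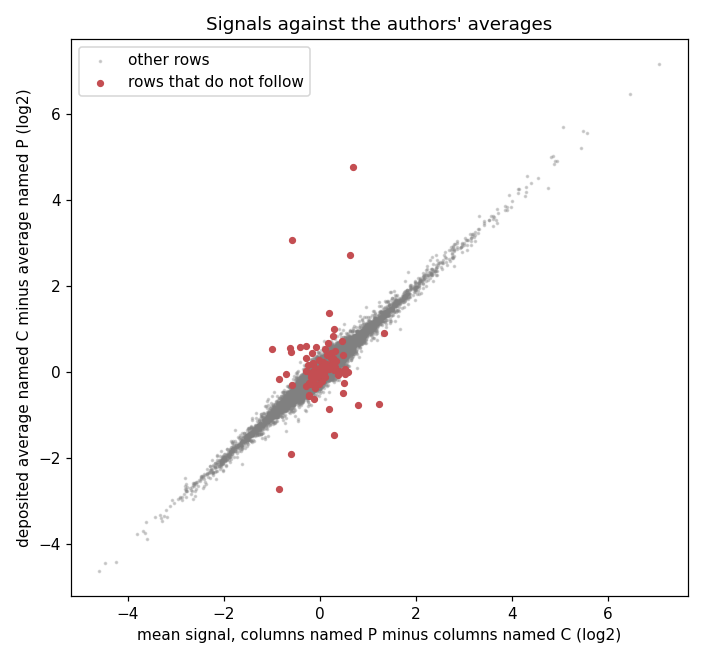
Difference of mean signals, columns named P minus columns named C (x axis, log2), against the difference of the authors' averages, C minus P (y axis, log2), for each row. Most rows lie along the diagonal, which shows the exchanged letters, while the 111 rows in red include several far from it.

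By sample label, 6391 rows (29.8%) passed an adjusted p of 0.05 in limma, 3160 higher and 3231 lower in libraries labelled anti-PD-1. The largest rises were in KCNK15, a potassium channel subunit (7.07 ± 0.20 SE on the log2 scale, adjusted p = 5.26e-06), CNN1, the smooth muscle protein calponin (6.46 ± 0.14, adjusted p = 2.8e-06), and KRT17, a keratin of stratified epithelia (5.56 ± 0.12, adjusted p = 2.8e-06). Mean signals of KCNK15 went from 5.76 ± 0.38 to 12.83 ± 0.17 (SD, n = 3 each). ANOS1, MAP2, IGFBP5, CEMIP, BCAM, SULT1E1, C1S, CLDN1 and ROS1 completed the 12, with rises between 4.75 and 5.49. The largest falls were in TCN1, a vitamin B12 binding protein (-4.59 ± 0.17, adjusted p = 1.08e-05), IL1RAPL1 (-4.46 ± 0.25) and EGR1, an early response transcription factor (-4.25 ± 0.14, adjusted p = 7.39e-06). FOSL1, a subunit of AP-1 (-3.81), and the ETS factor ETV1 (-3.68) came next, followed by PAQR5, HAS2, SPRY4, ARHGEF39, GPAT3, MYH15 and MMP13, with differences between -3.63 and -3.28. The file places KCNK15 on chromosome 20 from 44745780 to 44755077 and EGR1 on chromosome 5 from 138465490 to 138469315, with the build unsettled.

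**Figure D3:**
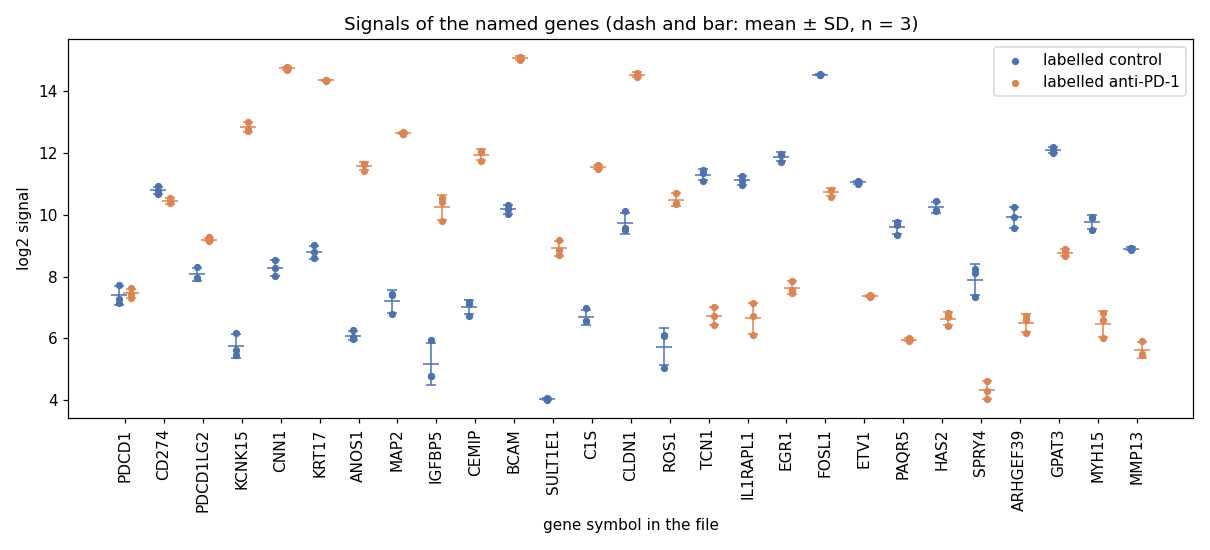
Log2 signal (y axis) of each named gene (x axis) in the 3 libraries labelled control (blue) and the 3 labelled anti-PD-1 (orange); points are libraries, dashes and bars the mean ± SD. Groups are apart for each gene except PDCD1, with means of 7.39 and 7.46.

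Unadjusted p lay under 0.05 in 8385 rows, where chance gives 1072, and groups did not overlap in 9335 rows (43.5%), where chance gives 10%. By the 2-fold rule at that unadjusted p, 1640 rows differed, 862 higher and 778 lower (793 and 849 after median centring, which also gave 2778 higher and 3673 lower past the adjusted threshold), and 1638 rows were both 2-fold and past the adjusted threshold. A 4-fold difference past the threshold was seen in 357 rows. The 2-fold rule was met by 1670 rows of the authors' deposited table, 880 of them higher in the group it names C and 790 higher in P, and 6439 had a false discovery rate under 0.05.

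PDCD1, which encodes the PD-1 receptor, differed by 0.07 ± 0.17 (adjusted p = 0.814). Its ligand CD274 was lower by a difference of -0.34 ± 0.10 (adjusted p = 0.0424), a call lost with a replicate block (adjusted p = 0.0948) and without any 1 library (adjusted p from 0.0596 to 0.126) except control replicate 2. The other ligand, PDCD1LG2, rose by 1.13 ± 0.12 (adjusted p = 0.000541). Of 20 genes for checkpoint receptors, ligands and exhaustion, 5 rose and 2 fell, including NT5E, the ectoenzyme CD73 (-3.21), PVR (0.74) and PVRL2 (1.13); the list did not pass (adjusted p = 0.21).

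The question of which gene groups moved was put to 37 lists, of which 8 passed camera with the preset correlation and 0 with an estimated one. Cell proliferation genes were lower, with a median of -1.55; 16 of 24 members fell and 0 rose (adjusted p = 2.17e-08, and adjusted p = 0.259 with an estimated correlation). The falls included BUB1, a spindle checkpoint kinase (-2.28), RRM2, a ribonucleotide reductase subunit (-2.23), AURKB (-2.17) and MKI67 (-1.75). A further 5 members, among them MCM2, MCM6 and BUB1B, belong to the 111 rows in conflict, and none of these 5 passed. Oxidative phosphorylation genes were lower by a small amount, with a median of -0.32; 11 of 18 fell and 0 rose (adjusted p = 0.000525, and adjusted p = 0.149 with an estimated correlation), including SDHB (-0.63), ATP5A1 (-0.60) and CYCS (-0.46). Of 8 heat shock genes 5 fell and 1 rose (adjusted p = 0.0216, and adjusted p = 0.282 with an estimated correlation; adjusted p = 0.0507 with rows below the median signal left out), with HSPH1 at -1.03 and HSPB1 at 0.52.

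Targets of YAP and TEAD, the transcription factors at the end of the Hippo pathway, were higher, with a median of 1.10; 11 of 13 rose and 0 fell (adjusted p = 1.12e-06, and adjusted p = 0.149 with an estimated correlation). ANKRD1 rose by 3.42, CTGF by 2.34, CRIM1 by 1.16 and CYR61 by 1.16. Among unfolded protein and integrated stress response genes 13 of 16 rose and 1 fell (adjusted p = 6.85e-05, and adjusted p = 0.149 with an estimated correlation). The members that rose included the ATF4 targets CHAC1 (2.42), ATF3 (2.04) and ASNS (1.65), while SDF2L1, an endoplasmic reticulum protein, fell (-0.78). Of 13 p53 targets 8 rose and 2 fell (adjusted p = 0.0197, and adjusted p = 0.261 with an estimated correlation): TP53INP1 by 3.41, EDA2R by 2.93 and CDKN1A by 0.46, against AEN (-1.26) and BAX (-0.62).

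Fibroblast and matrix genes were higher, with 9 of 19 rising and 0 falling (adjusted p = 0.00247, and adjusted p = 0.261 with an estimated correlation). COL1A2 rose by 3.15, LOX, a collagen crosslinking enzyme, by 1.69 and COL5A1 by 1.48. The other 10 members did not pass, among them COL1A1 (0.36), PDGFRA (0.21), DCN (0.03), POSTN (-0.43) and FAP (-0.58). Of 10 pericyte and smooth muscle markers 3 rose, CNN1, TAGLN (3.71) and DES (1.01), and the list passed (adjusted p = 0.0351, and adjusted p = 0.261 with an estimated correlation), but not without control replicate 2 (adjusted p = 0.0562). ACTA2, in both lists, is a row in conflict. Of 20 mesenchymal transition genes 10 are such rows, and the list, with 5 rising and 3 falling, did not pass camera (adjusted p = 0.0829); it did without anti-PD-1 replicate 2 (adjusted p = 0.0364) or 3 (adjusted p = 0.0471), and fry gave an adjusted p of 0.000477. These tests and counts include the 10 rows in conflict. CDH2, counted as rising by its signals, is such a row, so its direction is left open. Outside such rows SPARC rose by 1.75 and MMP14 by 1.04, while TNC (-0.51) and ITGA5 (-0.43) fell. Among 16 epithelial genes 6 rose and 3 fell (adjusted p = 0.641), with high signals of KRT8 in both groups (16.17 and 16.47).

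**Figure D4:**
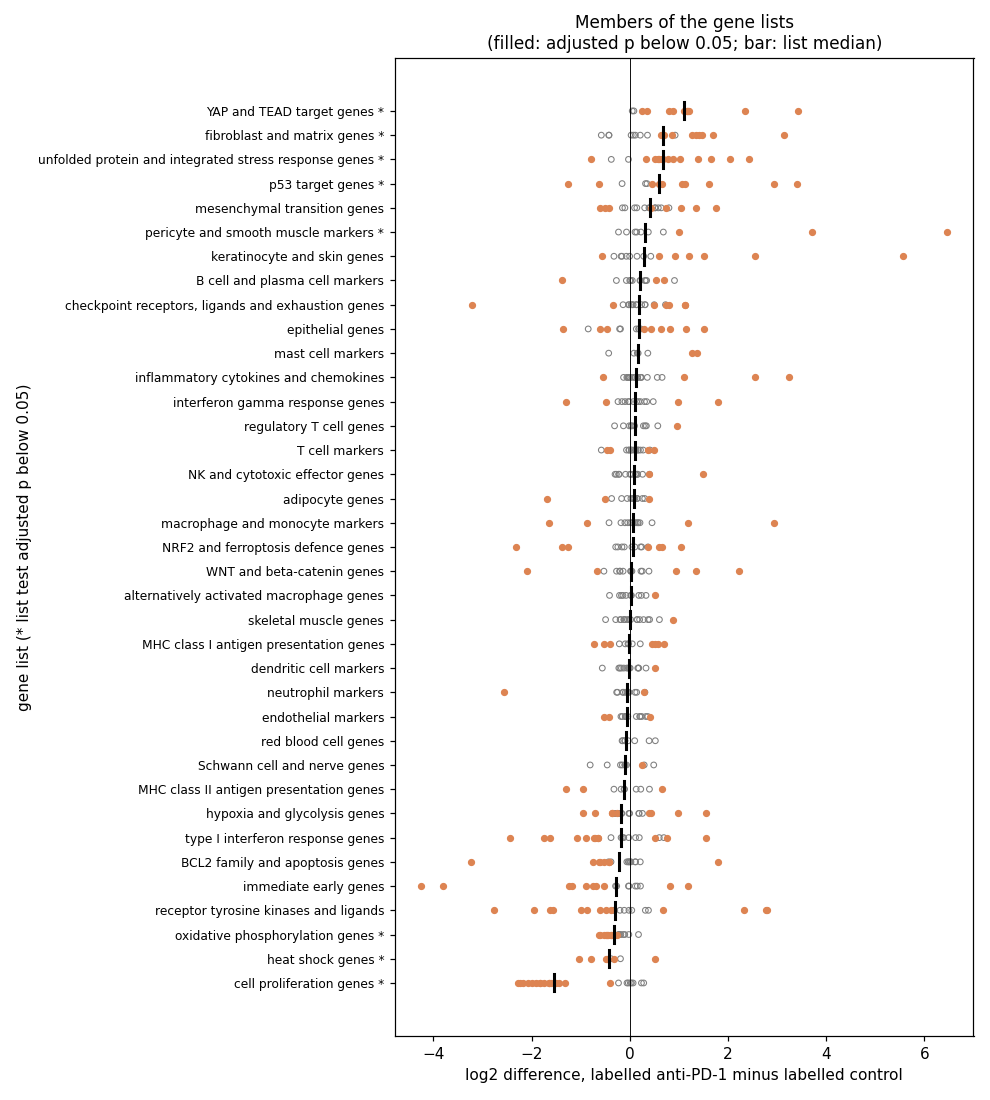
Log2 difference, libraries labelled anti-PD-1 minus control (x axis), of each member of the 37 lists (y axis); filled points passed an adjusted p of 0.05, bars are list medians and asterisks mark the 8 lists that passed camera. Medians run from -1.55 for cell proliferation genes to 1.10 for YAP and TEAD targets.

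In each list of blood and vessel cell markers most members lay below the median of all rows, though a few were bright. A mean signal below 5.09 was found in 25% of all rows, and 50% lay above the median by definition. Of 18 T cell markers 14 were below 5.09 and 0 above the median; 2 rose and 2 fell (adjusted p = 0.905). Below 5.09 were also 10 of 16 NK and cytotoxic effector genes, with 1 above the median (2 rose, 0 fell, adjusted p = 0.905), and 6 of 11 regulatory T cell genes, with 1 above it (1 rose, adjusted p = 0.389). Of 14 B cell and plasma cell markers 5 were below 5.09 and 2 above the median (2 rose, 1 fell, adjusted p = 0.585), and of 17 macrophage and monocyte markers 8 were below and 5 above (2 rose, 2 fell, adjusted p = 0.905). CD68, a lysosomal protein used as a macrophage marker, had mean signals of 14.40 and 12.76 in libraries labelled control and anti-PD-1, and APOE of 9.57 and 12.51. ADGRE1 (3.62 and 3.79) and LYZ (4.48 and 4.51) were among the macrophage markers below 5.09. Of 11 genes of alternatively activated macrophages 9 were below 5.09 and 0 above the median (1 rose, adjusted p = 0.931), of 14 neutrophil markers 8 and 1 (1 rose, 1 fell, adjusted p = 0.645), of 14 dendritic cell markers 5 and 3 (1 rose, adjusted p = 0.931) and of 7 mast cell markers 5 and 1 (2 rose, adjusted p = 0.249). Of 16 endothelial markers 8 were below 5.09 and 1, ENG, above the median at 15.13 and 14.71 (1 rose, 2 fell, adjusted p = 0.931), and of 8 red blood cell genes 4 and 1 (0 rose, 0 fell, adjusted p = 0.963). PECAM1 (4.32 and 4.25) and CDH5 (4.65 and 4.89) were among the endothelial markers below 5.09. Skeletal muscle genes (1 of 18 rose, adjusted p = 0.919), adipocyte genes (1 rose and 2 of 15 fell, adjusted p = 0.905) and Schwann cell genes (1 of 10 rose, adjusted p = 0.919) did not pass either.

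Of 21 type I interferon response genes 3 rose and 9 fell (adjusted p = 0.131), with OASL at -2.43, IFIT3 at -1.75 and MX2 at 1.55. Interferon gamma response genes went both ways, 2 of 16 up and 2 down (adjusted p = 0.84), as did MHC class I genes, 4 of 13 up and 3 down (adjusted p = 0.919), and MHC class II genes, 1 of 10 up and 2 down (adjusted p = 0.905). Among 24 cytokine and chemokine genes 3 rose, CXCL16 by 3.24, CCL2 by 2.56 and IL6 by 1.10, and CSF2 fell (adjusted p = 0.164 for the list). With rows below the median signal left out the list passed (adjusted p = 0.0412), its median going from 0.13 to 0.63, but not with rows below 5.09 left out (adjusted p = 0.0706). It also passed with members below 5.09 alone left out (adjusted p = 0.0396) and with fry (adjusted p = 0.00194). Of 15 keratinocyte genes 6 rose and 1 fell (adjusted p = 0.0829), and the list passed without anti-PD-1 replicate 2 (adjusted p = 0.031) and with fry (adjusted p = 0.000477). KRT14 stood at 1.51, but its mean signals, 3.43 in libraries labelled control and 4.94 in those labelled anti-PD-1, both lay below 5.09. Among brighter members PERP rose by 1.20 and SFN was the 1 that fell (-0.57). Of 17 immediate early genes 8 fell and 2 rose (adjusted p = 0.0832), DUSP1 being higher by 1.18; the list passed without control replicate 1 (adjusted p = 0.0477), with a replicate block (adjusted p = 0.0443) and with fry (adjusted p = 0.00269). Of 21 receptor tyrosine kinase and ligand genes 9 fell and 4 rose (adjusted p = 0.21): EREG at -2.76 and AXL at -1.63, against GAS6 at 2.77 and HBEGF at 2.32. BCL2 family and apoptosis genes (7 of 18 fell, 1 rose, adjusted p = 0.131) included BIRC5 at -3.24 and CFLAR at 1.79. Hypoxia and glycolysis genes (4 rose and 5 of 20 fell, adjusted p = 0.645), NRF2 and ferroptosis genes (4 rose and 3 of 16 fell, adjusted p = 0.931) and WNT genes (3 rose and 2 of 16 fell, adjusted p = 0.919) did not pass; HMOX1 stood at -2.32 and ADM at 1.55.

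Counts adjusted over the list alone were the same as those over all rows, except in these lists. Of the lists that passed, fibroblast and matrix genes had 10 rising, p53 targets 10 rising and 2 falling, and heat shock genes 1 rising and 6 falling. Adjusted over the list alone, 9 mesenchymal transition genes rose and 3 fell, 5 type I interferon genes rose and 10 fell, 3 immediate early genes rose and 9 fell, and 6 receptor tyrosine kinase and ligand genes rose and 10 fell. For hypoxia and glycolysis the counts were 4 and 7, for BCL2 family genes 1 and 8, for MHC class I genes 5 and 3, for epithelial genes 6 and 4, and for mast cell markers 3 and 1. They were 1 and 0 for NK and cytotoxic genes, 1 and 1 for B cells, 0 and 1 for neutrophils, 0 and 2 for endothelium and 0 and 0 for Schwann cells. The lists behind these counts include rows in conflict, such as CDH1 among epithelial genes and 10 of the mesenchymal transition genes. Median, mean and list test differed in sign for adipocyte, endothelial, red blood cell, dendritic cell, MHC class I and NRF2 lists, none of which passed.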

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

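Omission of the rows in conflict and the exchange of names were chosen after seeing the data. Over the alternatives, 149 of 158 counts stayed within 1.5 times their main value. Some of these were bound to stay: the workbook held the same signals, and the exchange of names only swaps higher and lower. The values of named genes and lists counted below also include the workbook's signals. With a further limit of 1.5-fold, 3705 of the 6391 changed rows remained (1900 higher, 1805 lower), fewer by construction. The 8 moved lists (5 higher, 3 lower) became 0 (0 higher, 0 lower) with an estimated inter-gene correlation and 22 (13 higher, 9 lower) with fry, which asks another question. With fry the NRF2 list, at a median of 0.07, was called lower where camera gave a higher direction without a call; the cause was not tested. Without each replicate in turn, changed rows ranged from 4901 to 5452 and 2-fold rows from 1633 to 1704, with 7 to 10 lists. The replicate numbers did not pair the libraries (correlations of deviations 0.013, -0.024 and 0.013; 2 of 6 libraries correlated best with their own number, and 0 pairs did so on both sides), and a replicate block gave 5363 rows; 1 row per gene symbol gave 6023 genes, and 1518 by the 2-fold rule. Without the 111 rows in conflict there were 6389 rows and 8 lists; with the group names exchanged, 3231 rows were higher and 3160 lower. Of 427 alternative values of the 27 named genes 421 kept their call and 6 lost it, each of them CD274; of 642 list values 611 kept theirs, 10 lost it, 20 gained one and 1 turned. Signals without background values leave the limit of detection unknown.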

Other observations

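The tests of the gene names, of the rows in conflict and of the MAPK genes were chosen after those patterns were seen, except the tests on genes that mice lack and the splits of the samples.

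The real grouping gave 6391 rows, 1640 rows by the 2-fold rule and 8 lists; the highest counts among the other splits of the 6 libraries were 0, 7 and 2. In each case 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05.

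The table pairs mouse array identifiers with human names, and 3 explanations were set against it. Names laid beside unrelated values are argued against by 31 of 31 sets of rows with the same 6 values sharing the first letters of their symbols, where shuffled symbols gave at most 3. Mouse values renamed through orthologs are argued against by all 18 of 18 listed genes that mice lack, such as CXCL8, IL32 and CD58, having a row with a value. That the probes were for human genes stays open: it was predicted that 3 or more of these 18 would have a mean signal above 11.04, where the brightest rows begin, and 1 did, MT1X, at 15.93. IL32 (10.8), MICB (10.58), MICA (10.5), CD58 (10.18) and CASP10 (8.2) lay below that bound but above the median of all rows, 7.743. The others ran from CEACAM6 (7.54) down to GNLY (3.28). Of 20878 rows annotated to an assembled chromosome, 5670 had an identifier that names the same chromosome. In most rows the mouse identifier and the human annotation thus name different chromosomes. No biological explanation was tested, and which species the RNA came from could not be decided here.

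In 111 rows the authors' averages (85 rows) or the SDs alone (26 rows) do not follow from the signals, and some of these gaps are small. Averaging or rounding is argued against for 26 rows, whose averages both lie outside all 6 signals. A gap over 1 was found in 32 rows. For rows with small gaps, or with SDs alone in conflict, another way of averaging or of computing SDs stays open. Scatter without regard to function is argued against by the lists: 10 of 20 mesenchymal transition genes are such rows, against 106 of 18620 genes (1-sided Fisher exact test over 37 lists, smallest adjusted p = 1.51e-16), and 5 of 24 cell proliferation genes are too (adjusted p = 3.92e-06). Signals entered by gene symbol may account for CDC42, whose 2 rows held the same signal in 5 of 6 libraries while their averages differed by 6.55 (named C) and 7.12 (named P), but rows of MSH6 and U2AF2 held the same signal in 0 libraries, so this cannot be told apart from other sources. Whether the signals or the averages are those measured stays open, and no biological explanation was tested.

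A hypothesis from the largest falls, EGR1, FOSL1, SPRY4 and ETV1, is that output of the MAPK pathway may be lower in libraries labelled anti-PD-1. Of 10 published output genes 8 fell and 1 rose, among them ETV4 (-3.07), PHLDA1 (-2.81) and DUSP6 (-2.66), while EPHA4 was higher (1.07). The 9 not already named had a median of -2.19 (unadjusted camera p = 2.53e-05 with the preset and p = 0.0119 with the estimated correlation), found and tested on the same data. These p-values do not compare with the adjusted ones of the lists. YAP and TEAD targets, at an unadjusted camera p of 0.00458 with the estimated correlation, did not pass once adjusted (adjusted p = 0.149). The immediate early list, which holds EGR1 and FOSL1, did not pass camera (adjusted p = 0.0832, and adjusted p = 0.6 with an estimated correlation). The median of all 10 was -2.40 after quantile normalization. Library medians already lay between 7.71 and 7.77, so that step could change little and cannot decide on scaling between libraries. The median difference over all rows was 0.013, so a shift common to all rows does not account for the falls. The direction stays open, since for 10 of 10 genes the letters of the authors' averages give the opposite one.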
